A study of Mus musculus with 9 samples.

How the data were processed

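RNA from the thalamus of wild-type mice was sequenced on day 7 in 9 samples, 3 each of the groups sham, stroke and mmpp. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the SMARTER mRNA kit for Illumina sequencing. Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and the genome build GRCm39 are named per the submitters' processing notes, without the role of each. The program that tested the groups is not given in the sources used here, nor is the setting for strand or for reads that match several genes. Near-identical genes are therefore uncertain, among those named below Hspa1a with Hspa1b, Hbb-bs with Hbb-bt, H2-Q1, Pcdha8, and the names Itgam and Lilrb4a, which each stand on 2 identifiers. Antisense and overlapping genes are uncertain for the same reason.

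The tables used here hold 1 row per gene and no value per library. Per the file headers, the authors deposited the mean TPM (a length-scaled share of all transcripts) of each group, a log2 fold change, a p-value and a q-value for stroke against sham and for mmpp against stroke. The deposited log2 fold change was checked to be the log2 ratio of the deposited mean TPM values, with a largest difference of 5.4e-11, so no pseudocount was added. A mean of 0.0001 TPM stands where a gene was not detected and is called the floor below, and no fold is given against it. A mean at the floor, or near 0 as for Junb in stroke, for Zfp715 in mmpp and for Taok1 in sham and mmpp, can also be a failed estimate or come from reads that match several genes, which group means cannot show. The sham means of Mki67, Msr1 and Il1rn, among others, were also near 0, and a fold against such a mean is uncertain in size. The tables list only genes with a p-value under 0.05 and an absolute log2 fold change of at least 1, as tested on the deposited values. A gene that is not listed may have missed either limit or may not have been tested, so absence from a table is not evidence that a gene did not change. Per-library counts were not analysed here. Depth, the spread between libraries and errors of single values are therefore unknown, and each mean is the authors' value.

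The design fixed before the data were examined foresaw a refit from values per library, and otherwise a description of the authors' deposited fold changes and adjusted p. The latter was done. The words rose, fell and changed are kept for genes with an authors' q-value under 0.05. Other genes are called listed higher or lower. The labels do not say whether a sample is 1 animal or a pool, so the p-values measure the spread between these samples, which may be partly technical.

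The deposited q-value was tested against the Benjamini-Hochberg formula. Where it is below 1, the p-value times the number of genes adjusted, divided by the q-value, gave a whole-number rank (tolerance 0.001), or the gene shared its q-value with another listed gene, for 96.4% of genes in stroke against sham and 99.8% in mmpp against stroke. The remaining genes were not used for ranks. This gave 20804 genes adjusted for stroke against sham and 19616 for mmpp against stroke. Listed genes with a q-value of 1 had been left out of that adjustment, 96 in the former table and 74 in the latter. The ranks also give the number of all adjusted genes, listed or not, at or below a p. In simulated tables of 20000 genes filtered in the same way, the number adjusted was recovered in 20 of 20 tables.

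The 39 gene lists and the rule for named genes were fixed before the data were examined. For each list and comparison, members listed higher and lower were set against all other listed genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over lists with at least 3 listed members. Genes are not independent replicates, and the test asks only whether the listed members lean to 1 side more than other listed genes do. In the simulated tables it called 20 of 20 planted lists and 2 of 600 random ones. The planted lists were almost wholly of lower genes, in tables whose changed genes were mostly higher. Short lists, and lower lists among mostly lower genes as in mmpp against stroke, were not simulated. A count adjusted over the list alone could not be given, since unlisted members have no p-value. The same test was run on the KEGG pathways that the authors' tables assign, with at least 10 listed genes. For pathways only listed genes with a pathway were compared, 1399 for stroke against sham and 349 for mmpp against stroke. Named genes were the 6 largest fold changes in each direction with a q-value under 0.05 and a symbol that is not a clone name, up to 3 members per list with the smallest q-value to a total of 30 per comparison, and the 10 genes listed in both tables with the smallest larger q-value. Conditions of that rule on values per library were dropped, as it provides. Genes named beyond it were chosen after their values were seen.

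For genes listed in both tables, directions were counted and set beside the number from independent lists and beside 100 simulated draws in which sham, stroke and mmpp groups shared the stroke libraries. The covariance of fold changes was not computed, since only selected genes have both. The share of the stroke-sham difference closed in mmpp was the log2 difference between mmpp and stroke divided by that between sham and stroke, with a bootstrap 95% interval over genes. Whether a list's members were listed in the opposite direction in mmpp more often than other genes was tested with Fisher's exact test and against 10000 random sets matched on stroke fold change and stroke TPM. The odds of opposite listing in genes higher and lower after stroke were pooled over strata of stroke fold change with the Mantel-Haenszel method, chosen after the shares were seen, and its interval treats genes as independent. Alternatives were other limits on the q-value, fold change and mean TPM, removal of genes at the floor, and pseudocounts of 0.1, 1 and 5 TPM.

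Identifiers and symbols are those of the authors' tables. Of the identifiers, 4066 of 4071 and 1021 of 1021 were found in GENCODE M21, an annotation of an older build, which was used only for gene types, so no coordinates are given. Computations used Python with numpy, pandas, SciPy and statsmodels, and figures used matplotlib. A result on 1 further group of genes is not reported here.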

Results

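Thalamic tissue of wild-type mice was compared on day 7 between 3 groups of 3 samples, called sham, stroke and mmpp. The study concerns photothrombotic stroke, in which a light-activated dye clots blood vessels, and an injected melanin nanozyme, a particle with enzyme-like activity, and it asks about glial activation and neuroinflammation. The abbreviation mmpp is not spelt out in the labels used here and is kept as given, and they do not say which groups were injected. Values are group means in TPM from the authors' tables. The depth of each library and the spread between libraries are not given by them.

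The stroke and sham groups were compared to ask which thalamic genes differed after the injury. Genes of microglia, phagocytes, cytokine signalling, antigen presentation, extracellular matrix and cell division rose, while genes of neurons, ion channels and the choroid plexus were lower. The authors' deposited table listed 4071 genes, 2469 higher and 1602 lower after stroke. Of these, 2713 had an authors' q-value under 0.05, of which 2012 rose and 701 fell. Listed higher genes took 3.42% of all TPM in sham and 20.6% in stroke, and listed lower genes took 13.6% in sham and 5.52% in stroke. The ranks recovered from the q-values placed at least 3150 of 20804 adjusted genes under a q-value of 0.05, so at least 437 further genes passed that limit and were not listed. Of 28 lists tested, 13 leaned toward higher and 7 toward lower genes. The 20 lists past the test became 15 among genes with a q-value under 0.05 and 2 under 0.01, where 86.5% of the genes compared were higher.

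Microglial genes were higher in both sets of markers. All 11 listed of 12 homeostatic microglia genes rose (adjusted Fisher's exact p = 0.00813), among them Tmem119, from 40.5 TPM in sham to 160.2 in stroke in the authors' deposited table. All 19 listed of 20 disease-associated microglia genes rose (adjusted Fisher's exact p = 0.000845). The secreted phosphoprotein gene Spp1 was at 34.7 TPM in sham and 5764 in stroke, 166-fold higher (q = 8.49e-29, authors' deposited table). Gpnmb was 153-fold higher and Lgals3, a galectin, 40.8-fold higher in the same authors' deposited table. Apoe, which carries lipids between cells, had 4212 TPM in sham and 35055 in stroke in the authors' deposited table. Of 22 genes of the lysosome and phagocytosis, 20 rose and none was listed lower (adjusted Fisher's exact p = 0.000845). Cd68 rose 68.6-fold, the scavenger receptor gene Msr1 271-fold and the progranulin gene Grn 14.3-fold in the authors' deposited table. Msr1 started from a mean of 0.0948 TPM in sham, near 0, so the size of its fold is uncertain.

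Immune signalling genes rose in several groups, each with an adjusted Fisher's exact p of 0.000845 unless given. All 17 listed of 22 cytokine and chemokine genes rose, and the authors' deposited table gave 76.9-fold for Ccl3, 44.8-fold for Ccl4 and 36.5-fold for the interleukin 1 receptor antagonist gene Il1rn. Il1rn had a mean of only 0.110 TPM in sham, so the size of its fold is uncertain. Of 21 innate receptor and inflammasome genes, 17 rose, with 32.6-fold for Tlr13, 13.4-fold for the inflammasome adaptor gene Pycard and 9.33-fold for Cd14 in the authors' deposited table. All 18 listed of 20 interferon response genes rose, with 19.4-fold for Zbp1, 8.57-fold for Bst2 and 7.95-fold for Oas1a in the authors' deposited table. All 17 antigen presentation genes rose. Of 16 complement genes, 14 rose (adjusted Fisher's exact p = 0.00292), and C1qa went from 284.9 to 5321 TPM in the authors' deposited table. All 7 listed of 10 oxidant-producing enzyme genes rose, but the lean of that list did not pass (adjusted Fisher's exact p = 0.0601). The antioxidant enzyme list of 19 genes also holds some that do not encode enzymes, among them the transcription factor gene Nfe2l2. Of its members only Hmox1 and Nfe2l2 were listed, and both rose, 16.8-fold and 5.04-fold in the authors' deposited table.

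Genes of other non-neuronal cells were also higher. Of 16 reactive astrocyte genes, 12 were listed higher, 11 of them with a q-value under 0.05, and Hspb1 fell (adjusted Fisher's exact p = 0.0290). Gfap, the astrocyte filament gene, rose 6.25-fold and Lcn2 rose 21.5-fold in the authors' deposited table. A1-named astrocyte genes were listed 9 higher and 2 lower (adjusted p = 0.255) and A2-named ones 7 higher and 0 lower (adjusted p = 0.0601), neither past Fisher's exact test. Homeostatic astrocyte genes had 1 listed higher, Aqp4, and 1 lower, Slc6a11. Of 20 genes of mural cells, fibroblasts and matrix, 18 were listed higher, 17 with a q-value under 0.05 (adjusted Fisher's exact p = 0.000845). The macrophage elastase gene Mmp12 rose 308.0-fold, Col3a1 48.8-fold and Col1a1 36.4-fold in the authors' deposited table. Markers of infiltrating myeloid cells had 11 of 16 listed higher, 10 of which rose (adjusted Fisher's exact p = 0.00813), and lymphocyte markers had 9 of 19, 5 of which rose (adjusted Fisher's exact p = 0.0223). All 15 cell division genes rose (adjusted Fisher's exact p = 0.00195), with 168-fold for the proliferation marker Mki67 and 122-fold for Top2a in the authors' deposited table. The sham mean of Mki67 was 0.0309 TPM, near 0, which leaves the size of its fold uncertain.

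Neuronal genes were lower. The gain of TPM by genes higher after stroke by itself shifts all other genes by -0.28 on the log2 scale. This shift was not removed from the values below. The listed pan-neuronal members had a median log2 fold change of -1.33. Of 14 pan-neuronal genes, 8 were listed lower, 6 of which fell (adjusted Fisher's exact p = 0.00161). Snap25, of the synaptic vesicle fusion machinery, fell from 674.8 to 258.3 TPM in the authors' deposited table. Thalamic relay neuron genes had 7 of 16 listed lower, 4 of which fell (adjusted Fisher's exact p = 0.00292). The vesicular glutamate transporter gene Slc17a6 fell 3.07-fold, Rora 3.38-fold and Tcf7l2 2.68-fold in the authors' deposited table. Synaptic signalling genes had 7 of 22 listed lower, 3 of which fell (adjusted Fisher's exact p = 0.00292), and voltage-gated channel genes 9 of 22, 4 of which fell (adjusted Fisher's exact p = 0.000845). Inhibitory neuron genes had 5 of 11 listed lower (adjusted Fisher's exact p = 0.0156). Of these, 2 fell, too few for that test among genes with a q-value under 0.05. Immediate early genes, which neurons switch on with activity, had 6 of 16 listed lower, 4 of which fell, and 1 higher, Egr2 (adjusted Fisher's exact p = 0.0254). Fos fell 5.66-fold in the authors' deposited table. The choroid plexus, which makes cerebrospinal fluid, had 8 of 10 marker genes listed lower, 6 of which fell (adjusted Fisher's exact p = 0.00161). Its transthyretin gene Ttr fell from 4317 to 371.7 TPM in the authors' deposited table. Cerebellar markers, in a list written after members had been seen, had 10 of 30 listed lower, 3 of which fell, and 1 higher, though Pvalb is also in the inhibitory neuron list and Kcnd2 in the channel list.

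The remaining lists showed no lean that passed. With 3 members higher and 0 lower, a list could only reach a Fisher's exact p of 0.284, and with 6 and 0 only 0.0876. Lists of those sizes could therefore not pass, and the test decides nothing for them. Axonal injury genes had 3 listed higher and 1 lower (adjusted p = 1), oligodendrocyte precursor genes 3 higher (adjusted p = 0.305), endothelium and barrier genes 3 higher (adjusted p = 0.305), iron handling and ferroptosis genes 6 higher (adjusted p = 0.107), and growth factor genes 4 higher and 1 lower (adjusted p = 0.679), each by Fisher's exact test. Too few members were listed to test ependyma (2 higher), erythrocytes (2 lower), hypothalamus (1 lower), cortex and hippocampus (1 higher, 1 lower) and mitochondrially encoded genes (1 higher). No member was listed for myelin and oligodendrocytes, habenula, striatum, or the Y-linked and Xist check.

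The largest fold changes with a q-value under 0.05 were mostly of genes at the floor in 1 group. The authors' deposited table put Kctd12, Mmp13, Gdf3, H2-Q1, Nxpe1-ps and Prnd at the floor in sham, and at 24.5, 7.46, 3.02, 2.86, 2.51 and 2.37 TPM in stroke. It put Rn7s6, Glb1l3 and Pcdha8 at the floor in stroke. The dopamine transporter gene Slc6a3 fell from 18.8 to 0.225 TPM, Junb from 11.8 to 0.0308 and Spink4 from 4.68 to 0.0627 in the authors' deposited table. Means this near 0, that of Junb included, can be failed estimates. Of 241 KEGG pathways, 98 leaned to 1 side past Fisher's exact test. Cytokine-cytokine receptor interaction had 79 genes listed higher and 5 lower (adjusted p = 5.75e-07), NF-kappa B signalling 42 and 0 (adjusted p = 4.92e-06), synaptic vesicle cycle 3 and 20 (adjusted p = 4.94e-06) and oxidative phosphorylation 4 and 20 (adjusted p = 1.03e-05), by Fisher's exact test.

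**Figure D1:**
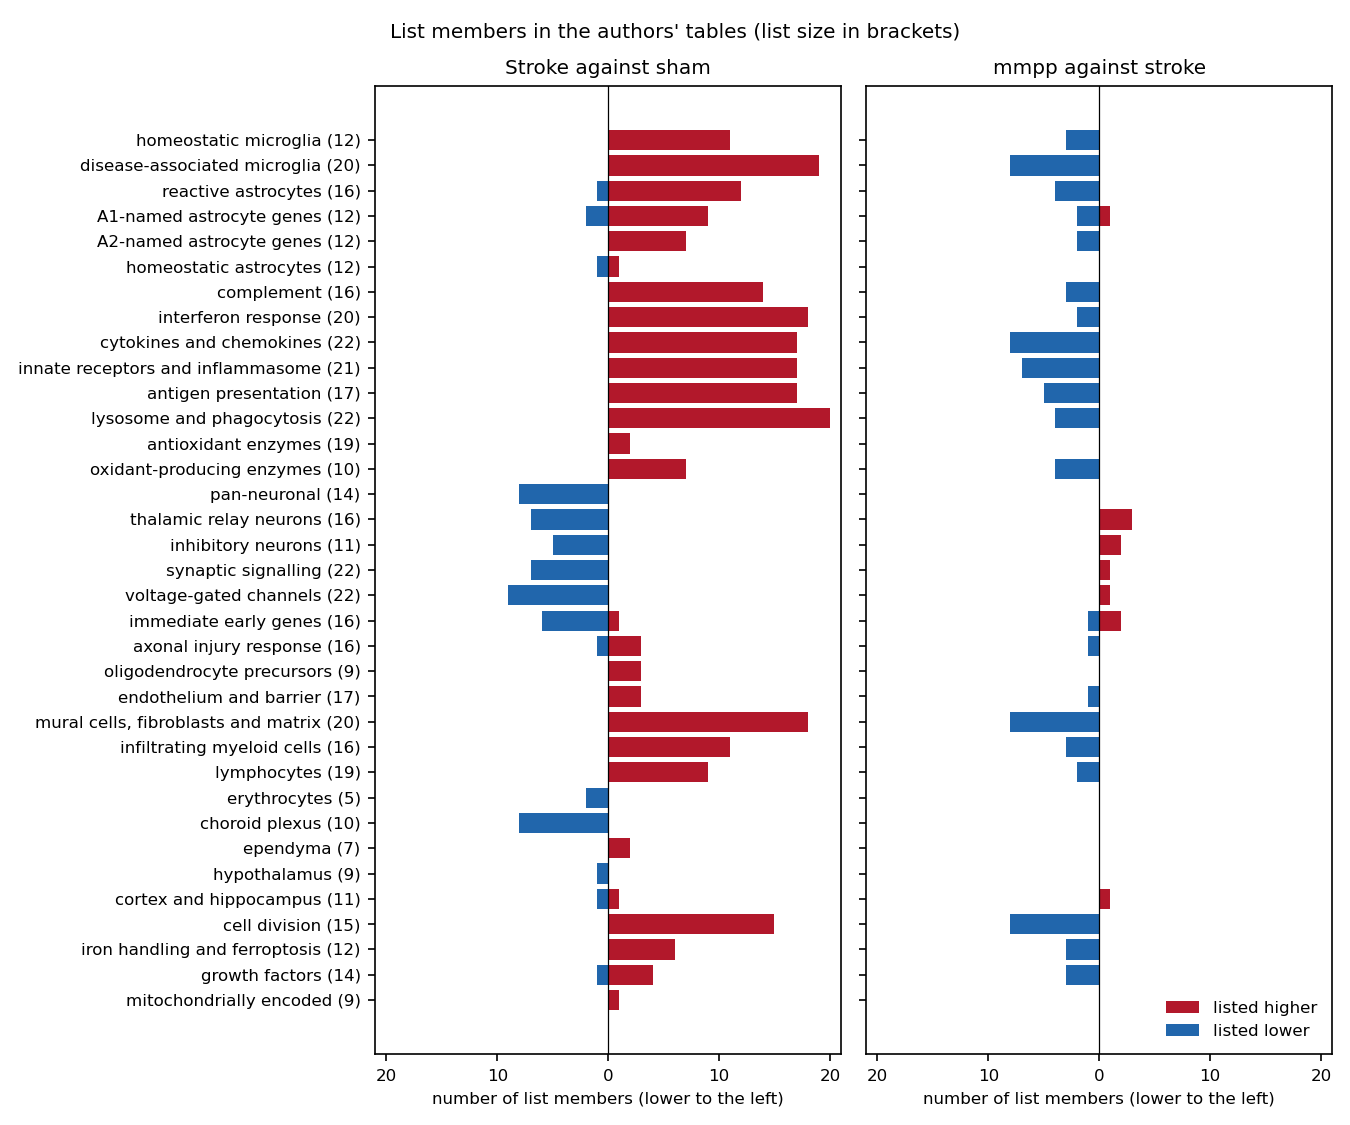
Number of members of each fixed list in the authors' tables, for stroke against sham (left panel) and mmpp against stroke (right panel), with red bars for members listed higher and blue bars to the left for members listed lower. Lysosome and phagocytosis had 20 members listed higher after stroke and 4 listed lower in mmpp.

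The mmpp and stroke groups were compared to ask which genes differed between them. Few genes passed adjustment. The authors' deposited table listed 1021 genes, 264 higher and 757 lower in mmpp, of which 8 had a q-value under 0.05. In it, Zfp715 fell 40.5-fold (q = 1.47e-12), Taok1, a kinase gene, 18.4-fold (q = 0.000832), Gucy1a3, a subunit of the nitric oxide receptor, 10.7-fold (q = 8.67e-08), 1 of the identifiers named Lilrb4a, a myeloid receptor, 9.66-fold (q = 0.0344) and Fmn1 4.90-fold (q = 0.0219). Zfp715 was at 1.25 TPM in sham, 3.32 in stroke and 0.0821 in mmpp, and Taok1 at 0.178, 3.25 and 0.177, in the authors' deposited tables. Means this near 0 can be failed estimates, and for Taok1 the stroke mean is the one that stands apart. Gm13431 was at 2.81 TPM in stroke and at the floor in mmpp (q = 0.00931, authors' deposited table). The nuclear receptor gene Nr4a3 rose 5.18-fold (q = 0.00253) and the serotonin receptor gene Htr1b 9.24-fold (q = 0.0110) in the authors' deposited table. The recovered ranks placed 1187 of 19616 adjusted genes at a p of 0.05 or below, where chance gives 981. At a p of 0.001 or below they placed 71, where chance gives 19.6. For stroke against sham the same counts were 5591 and 2032.

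**Figure D2:**
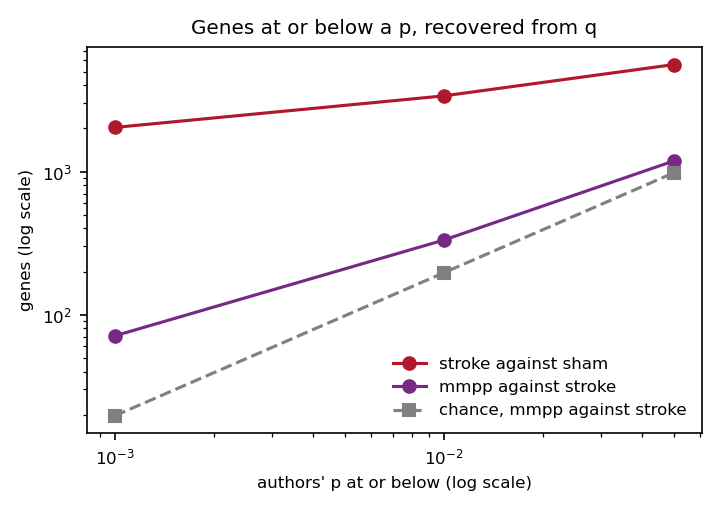
Number of genes at or below an authors' p, recovered from the q-values, against that p, both on log scales, for both comparisons and for chance in mmpp against stroke. The mmpp line lies at 71 genes for a p of 0.001, against 19.6 by chance, and at 1187 for 0.05, against 981.

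No member of the 39 lists passed a q-value of 0.05 in mmpp against stroke, so the following are listings at an unadjusted p under 0.05. Disease-associated microglia genes had 8 of 20 members listed lower and none higher. Spp1 was at 5764 TPM in stroke and 1245 in mmpp (q = 0.328), Cd9 at 1370 and 372.9 (q = 0.395) and Lpl at 132.0 and 31.9 (q = 0.510) in the authors' deposited table. Cytokines and chemokines had 8 of 22 listed lower, among them Ccl3 at 171 and 39.3 TPM (q = 0.204), Ccl4 at 79.9 and 24.2 (q = 0.510) and Tnf at 3.55 and 0.888 (q = 0.334) in the authors' deposited table. Mural, fibroblast and matrix genes also had 8 listed lower, with Dcn at 40.6 and 11.2 TPM, Acta2 at 79.6 and 32.7 and Postn at 6.78 and 2.23 in the authors' deposited table, as did cell division genes, with Mki67 at 5.21 and 1.44, Plk1 at 23.2 and 7.87 and Ccna2 at 13.2 and 5.07 in the authors' deposited table. Innate receptors and inflammasome had 7 listed lower, among them the cell death genes Mlkl, Casp1 and Casp8. Antigen presentation had 5 listed lower, with Cd74 at 299 and 100.5 TPM, H2-Ab1 at 198 and 71.5 and H2-Eb1 at 117 and 46.8 in the authors' deposited table.

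Further lists had fewer members in mmpp against stroke. Lysosome and phagocytosis, reactive astrocytes and oxidant-producing enzymes had 4 each listed lower, the astrocyte genes being Lcn2, Cp, Timp1 and Nes. Homeostatic microglia, complement, infiltrating myeloid cells, iron handling and growth factors had 3 each listed lower, and interferon response, A2-named astrocyte genes and lymphocytes 2 each. A1-named genes had 2 lower and 1 higher, and axonal injury and endothelium 1 lower each. Thalamic relay neurons had 3 listed higher, Slc17a6, Gbx2 and Plekhg1, and Slc17a6 was at 20.7 TPM in stroke and 55.3 in mmpp (q = 0.772, authors' deposited table). Inhibitory neuron genes had 2 listed higher, Sst and Vip, immediate early genes 2 higher, Fos and Fosb, and 1 lower, Egr3, and synaptic signalling, voltage-gated channels and cortex and hippocampus 1 higher each. The last pair, Kcnd2 and Neurod1, are also cerebellar markers, of which 9 of 30 were listed higher and 0 lower in this comparison, in a list written after members had been seen. The other lists, choroid plexus, pan-neuronal and antioxidant genes among them, had no listed member. None of 17 lists tested leaned to 1 side past Fisher's exact test after adjustment. At an unadjusted p under 0.05 there was 1, thalamic relay neurons (Fisher's exact p = 0.0172, adjusted p = 0.293). Lists with only lower members could not pass at these sizes, since only 25.9% of the genes listed in this comparison were higher. With all 8 listed members lower the Fisher's exact p was 0.121, and shorter lists gave larger values. For such lists the test decides nothing. Of 61 KEGG pathways, 1 differed from the other listed genes with a pathway, neuroactive ligand-receptor interaction, with 16 genes listed higher and 16 lower (adjusted Fisher's exact p = 0.000807).

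Genes listed in both tables were counted by direction, which asks whether genes that differed after stroke differed the other way in mmpp. Most mmpp-listed genes did. Of 815 genes in both of the authors' tables, 639 were higher after stroke and lower in mmpp, 174 were lower after stroke and higher in mmpp, and 2 had the same direction, Zfp420 and Mfrp. The 813 opposite genes were 79.6% of the 1021 listed for mmpp. Both comparisons use the same stroke libraries, and chance high or low values there push the directions apart. With no difference between any groups, simulated draws gave 18.4% on average (15.2% to 21.6%). With stroke effects as large as observed and mmpp equal to stroke they gave 30.9% (27.8% to 33.8%). The draws assume independent genes and equal noise in all groups, and they select on p alone, without the fold limit of the authors' tables. Independent lists would share 95.3 genes higher then lower and 21.6 lower then higher. The simulation leaves out effects of the mmpp group and the independent lists leave out the shared libraries, so the excess over neither is the size of a shared effect, and part of it may come from the shared libraries, which could not be split. Only 5 opposite genes had a q-value under 0.05 in both tables.

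The genes with the smallest q-values over both tables were Taok1, Nr4a3, Gm13431, Fmn1, Lilrb4a, Lmo2, Gm1305, Hspa1b, Hspa1a and Prr11. Prr11 was tied for the last place with Abcg3, BE692007 and 9930111J21Rik2 (q = 0.0972 for mmpp against stroke). Nr4a3 was at 5.75 TPM in sham, 1.07 in stroke and 5.56 in mmpp in the authors' deposited tables. Lmo2, a transcription cofactor gene, was at 13.5, 176 and 24.2 TPM (q = 0.0566 for mmpp against stroke) in the authors' deposited tables. The heat shock gene Hspa1a was at 98.6, 7.69 and 64.3 TPM (q = 0.0707 for mmpp against stroke) in the authors' deposited tables.

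**Figure D3:**
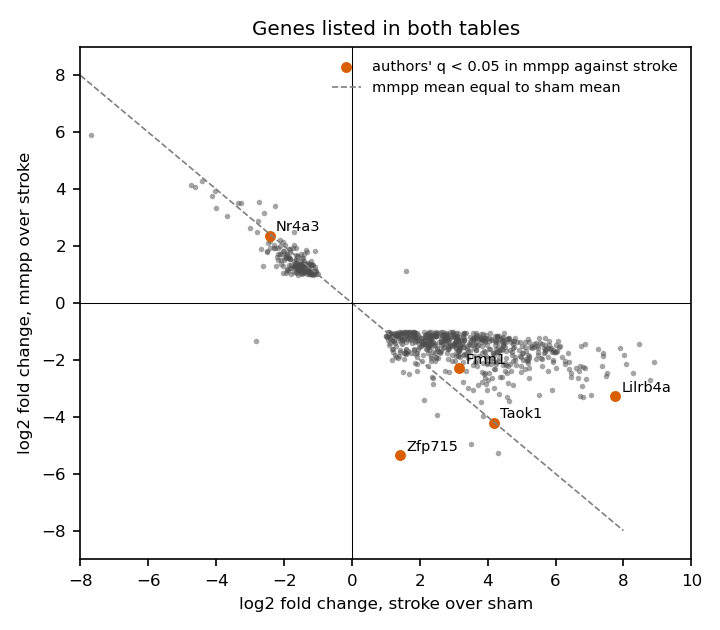
Log2 fold change of mmpp over stroke against that of stroke over sham for genes listed in both of the authors' tables and not at the floor in any group, 1 point per gene, with genes under a q-value of 0.05 in mmpp against stroke in orange. Of 753 such genes, 1 (Gm45717) lies outside the axes, and on the dashed line the mmpp mean equals the sham mean.

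Over the 813 opposite genes, the median share of the stroke-sham difference closed in mmpp was 0.586 (95% bootstrap interval over genes 0.550 to 0.627, quartiles 0.385 and 0.867). The bootstrap intervals here treat genes as independent and leave out the spread between samples. Simulated draws gave a median of 0.813 (0.755 to 0.854) with mmpp equal to stroke, and about 1 with no group differing, on the scale of the test statistic, so a share above 0 among genes selected in this way does not by itself show that mmpp differed from stroke. The share was 0.484 (0.464 to 0.509) for the 639 genes higher after stroke and 0.879 (0.848 to 0.900) for the 174 lower. The authors' mean was still above sham in mmpp for 86.9% of the former and below sham for 75.9% of the latter. These shares cover listed genes only, and a gene with a small stroke difference had to close most of it to be listed. Of genes higher after stroke, 25.9% were listed lower in mmpp, and of genes lower after stroke 10.9% were listed higher. Both shares grew with the stroke fold change, from 7.89% in the fifth of higher genes with the smallest to 44.7% in that with the largest, and from 2.18% to 24.9% in lower genes. The odds of opposite listing were 2.87 times as high in higher as in lower genes, and 1.22 times (95% interval 0.993 to 1.51) when pooled by the Mantel-Haenszel method over 10 strata of the size of the stroke fold change, a comparison added after the shares were seen. That interval includes no difference. No list stood out from other genes in this. Of 28 lists tested, 0 passed Fisher's exact test after adjustment (smallest adjusted p = 0.390) and 1, cell division with 8 of 15 genes, had an unadjusted p under 0.05 (p = 0.0320). With sets matched on stroke fold and TPM 0 passed either.

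**Figure D4:**
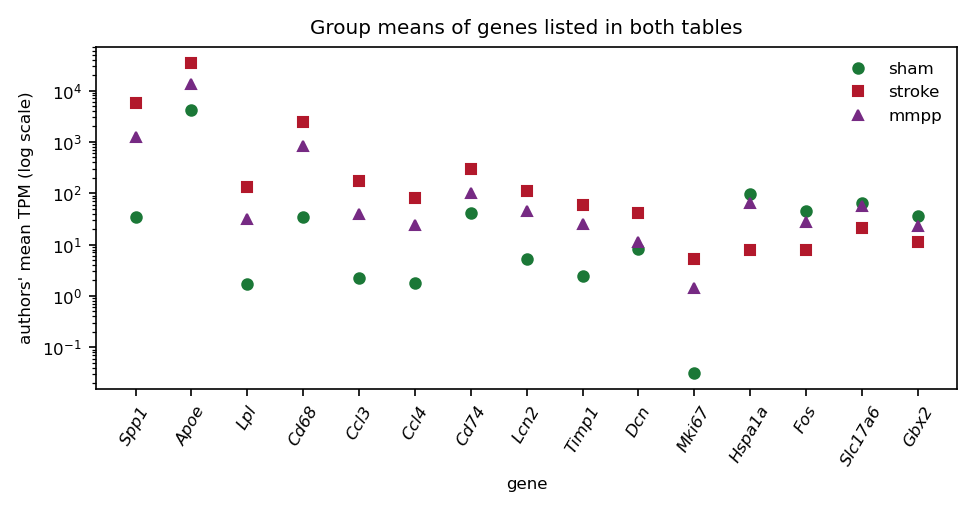
Authors' mean TPM on a log scale in sham (circles), stroke (squares) and mmpp (triangles) for 15 genes listed in both tables, which were chosen after their values were seen. Spp1 had means of 34.7 in sham, 5764 in stroke and 1245 in mmpp, and Slc17a6 63.7, 20.7 and 55.3.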

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

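The limits on a q-value of 0.01, a log2 fold change of 1 and the lowest 10% of mean TPM were planned, and the other settings were chosen after seeing the data. For stroke against sham, 4071 listed genes became 1908 at a q-value under 0.01, 2713 under 0.05 and 1623 at a log2 fold change of at least 2. The share listed higher went from 60.6% to 86.5%, 74.2% and 87.3% under these, and to 58.5% without the lowest 10%. For mmpp against stroke, 1021 listed genes became 5, 8 and 303, and the share higher went from 25.9% to 20% at a q-value under 0.01. The count of opposite genes went from 813 to 3 and 5 at q-values under 0.01 and 0.05 in both tables and to 187 at a log2 fold change of at least 2 in both. With a q-value under 0.05 after stroke alone it was 690, and without genes at the floor 751. The median share closed went from 0.586 to 0.633, 0.700 and 0.738 with 0.1, 1 and 5 TPM added and to 0.512 with a q-value under 0.05 after stroke. Stricter limits leave fewer genes by construction, and the cause of the other shifts was not tested. Lists past the direction test after stroke went from 20 to 2 at a q-value under 0.01, where 86.5% of the genes compared were themselves higher, and were 15 under 0.05. The count of 0 lists in the test of opposite listing stayed at 0 under the settings run. In mmpp against stroke the q-value limits left no list member, so they test nothing there. A log2 fold change of at least 1 removed no gene and tests nothing, and a constant added to both means cannot turn the sign of a named gene.

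No paired analysis was possible because the tables used hold group means and no value per library. For the same reason other scalings, another test, a refit with a filter on low values or a pseudocount, leaving out libraries in turn and other splits of the samples were not run, and what depth limits is unknown.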

Other observations

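Apart from the test of further choroid plexus markers, which were listed before they were looked up, the tests in this part were chosen after the values were seen. Cytosolic heat shock genes, a list written after some members had been noticed, had 6 of 13 members lower after stroke, all of which fell (Fisher's exact p = 0.00371). Hspa1a fell 12.8-fold and Dnajb1 4.28-fold in the authors' deposited table. In mmpp Hspa1a, Hspa1b and Dnajb1 were listed higher. Of 13 chaperones of the endoplasmic reticulum, Calr, Hsp90b1, Pdia3 and Sdf2l1 rose after stroke, and the lean of this list did not pass (Fisher's exact p = 0.159). Members of both lists had been noticed before the lists were written, so these tests decide nothing about the groups. Hspa5, the main chaperone of that compartment, was at 242.0 TPM in stroke and 58.6 in mmpp (q = 0.145, authors' deposited table).

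Genes in both tables lay almost without exception on opposite sides. Among 732 genes higher after stroke with a q-value under 1e-06, 279 (38.1%) were listed lower in mmpp and 0 higher. Independent noise of single genes in the shared stroke libraries would give about 27.6 lower and 11.8 higher (exact binomial p = 9.43e-196). The size of that noise was taken from the authors' p-values, assuming equal noise in all groups and leaving out the fold limit of the listing. The p treats genes as independent, so it does not measure how far the groups differ. Of the other genes that both tables list, 534 were opposite and 2 were not, where simulated draws with mmpp equal to stroke gave 253 to 321 and 31 to 62. Those draws rest on assumed settings, so noise stays open for these genes. Stroke libraries that as a group lay further from sham, through a larger injury or another piece of tissue, cannot be told apart from an effect of what was done to the mmpp group, because the median share closed of 0.484 in higher genes is bounded by the listing limit and no value per library was used, and that effect is likewise untested.

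The choroid plexus markers were lower after stroke, with a median log2 fold change of -2.23 over the 8 listed. The gain of TPM by higher genes shifts all others by -0.28 on the log2 scale, too little by itself to bring a gene to the listing limit of 1. That limit bounds the median of listed members, so the median is no test of this shift. The smallest absolute log2 fold change among the 8 was 1.43. Less choroid plexus tissue in the stroke samples predicts that further markers fall as well. Of 18 such genes, 12 were listed lower, 9 of which fell, and 0 higher (Fisher's exact p = 1.36e-05), which is consistent with that explanation, and Ttr was the most abundant marker at 4317 TPM in sham. Of the 10 fixed markers, Otx2 is also in the inhibitory neuron list. Marker levels cannot tell less tissue from lower expression within it. Whether any loss of tissue came from the injury or from dissection was not tested.

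Markers of the cerebellum, which the labels do not name as sampled, were listed higher in mmpp for 9 of 30 genes and lower for 0. Pcp2, a Purkinje cell gene, was at 2.94 TPM in stroke and 20.7 in mmpp, Ppp1r17 at 1.07 and 6.84 and Gabra6 at 0.0705 and 0.656 in the authors' deposited table, none with a q-value under 0.05. Cerebellar tissue in the mmpp samples is a candidate explanation, but the 9 markers listed higher were known when the list was written, so its test decides nothing. Calb1 and Kcnd2, 2 of the 9, are also among 10 markers listed lower after stroke, and thalamic neurons express some of the markers too.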
